A study of Mus musculus with 2 samples.

How the data were processed

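The data came from 2 droplet single-cell RNA libraries of mouse soft tissue around the Achilles tendon, 1 from an injured limb and 1 from the contralateral uninjured limb. Per the labels, both carried the genotype Hoxa11-CreERT2 with a Cre-dependent rtTA allele and a TetO-Vegfd transgene, and the injury was a burn with tenotomy 7 days before collection. The uninjured library was also labelled burn/tenotomy, so it was not from untreated mice. The tissue was digested with collagenase and dispase and filtered, and 10x Genomics 3' libraries were made, per the submitters' protocol notes. The deposited matrices hold raw UMI counts per gene and barcode, per the file headers and the whole-number values. They were made with Cell Ranger 5.0.1 on the mm10 genome, per the submitters' processing notes and the file headers. The annotation release and the cell calling settings are not given in the sources used here, and no deposited barcode held fewer than 500 UMIs. Whether each library pooled several animals is not given in the sources used here. Libraries from control mice without the transgene were not analysed here.

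Cells with 500 or more detected genes and at most 10% mitochondrial UMIs were kept. Scrublet, as implemented in scanpy 1.11.5, was run on each library alone. Its automatic thresholds marked 1 injured and 3 uninjured cells, so cells with a score above 0.2 were removed instead, a threshold set after the data were examined. That removed 215 of 9366 injured cells (2.30%) and 60 of 4760 uninjured cells (1.26%). Doublets of like cells and free RNA in droplets were not removed, so levels at or near those of other cell types were read as background. Doublets of unlike cells may also remain. For 10691 and 6850 deposited barcodes, the shares removed were below the rate of 0.8% per 1000 barcodes used in an alternative. A cluster of 356 kept cells had markers of pericytes or smooth muscle and of vascular endothelium, at 2.02 times the library median depth. It stayed unnamed, and whether its cells are doublets was not tested.

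Counts of the 13851 cells kept were scaled to 10000 UMIs per cell and log transformed. The 2000 most variable genes, picked over both libraries with mitochondrial, ribosomal, haemoglobin, immunoglobulin and sex-linked genes left out, 30 principal components and 15 exact nearest neighbours (scikit-learn 1.9.0) were used for Leiden clustering (igraph 0.11.9) at resolution 0.8 with random seed 1. Both libraries were clustered together without batch correction, since library and injury coincide. Each of the 34 clusters was named from 24 marker lists fixed before the data were examined, by the list with the highest mean log2 ratio over other cells and at least 3 markers in 10% or more of its cells. Further naming rules were set after the data were examined. A cluster stayed unnamed if it was under 1/3 of its library's median depth with no marker of its class among its 10 top genes. It also stayed unnamed if a list of another class with 5 or more detected markers reached 0.75 of the best score, or if its 10 top genes held more markers of another class than of its own. The pseudocount behind the top genes, 1 UMI per 10000, was set after the data were examined. The names mesenchymal (clusters named by the fibroblast, tenocyte and chondrocyte lists) and mononuclear phagocyte (macrophage, monocyte and osteoclast-like clusters) cover several lists.

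With 1 library per group no test of injury is possible, and no p-value is given. Cells are not replicates. Shares carry exact Clopper-Pearson 95% intervals and summed counts carry exact Poisson 95% intervals, and ratios carry the matching conditional exact intervals. All cover counting error only, not variation between mice. For 0 counts, a limit of 3 counts was used. Folds given as at least a value rest on that limit and can exceed the lower end of the exact interval. For Krt14 over all cells that lower end was 12618-fold. UMIs were summed per library and class and scaled to 1000000 UMIs of the class total (CPM). Log2 ratios, injured over uninjured, used a pseudocount of 5 CPM. The median log2 ratio over all genes lay within 0.06 of 0 in each main comparison, between -0.06 in mesenchymal cells and 0.04 in vascular endothelial cells. Over genes with 50 or more UMIs in both libraries, the median log2 ratio in mesenchymal cells was -0.12, so a median-of-ratios scale raises every mesenchymal log2 ratio by that amount. Classes with 50 or more cells in both libraries were compared. The named genes were the 12 with the highest and the 12 with the lowest log2 ratio among genes at 50 CPM or more in at least 1 library. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes and unnamed gene models were left out. Within a class, a gene was named only if its level reached 0.2 of its highest level in any other class of that library. Members of the gene lists could also be named from their list.

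The 21 gene lists, fixed before the data were examined, covered VEGF ligands, receptors and processing, lymphatic endothelial function, tip cells and sprouting, chondrogenic and osteogenic genes, osteoclasts and resorption, BMP and TGF-beta signalling, fibrillar matrix, matrix proteases and inhibitors, activated fibroblasts, resting fibroblast progenitors, tendon, inflammatory cytokines and chemokines, resident and resolving macrophages, wound and lipid-associated macrophages, interferon response, MHC class II, cell cycle, hypoxia and glycolysis, dissociation and immediate early genes, the driver gene with positional Hox genes, and sex-linked genes. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description and not as a test. Members under 1 CPM in both libraries were left out, and 1 list gene was absent from the reference. Cycling cells were those with an Mki67 or Top2a UMI after cells with 2000 or more UMIs were thinned to 2000, and 460 injured and 185 uninjured cells with fewer were left out. Cells were assigned a sex from Xist UMIs only or UMIs of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty only. Gene positions came from GENCODE M21, which held 32235 of the 32285 gene IDs.

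Alternatives fixed before the data were examined were other limits on genes and mitochondrial share, doublets kept, other clustering resolutions, list genes left out of clustering, each library clustered alone, other pseudocounts and scales, a mean over cells, a filter on low genes, other thinning depths and a higher UMI minimum for sex. Alternatives chosen after seeing the data were doublets removed by rank at 0.8% per 1000 barcodes, keratinocyte-like cells left out, cells of 1 sex only, list members at free RNA level left out, a tenocyte-like or a shallow osteoclast-like cluster left out, and each cluster with over 100 cells of each library taken alone.

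The comparison step, from summed UMIs onward, was tested on simulated sums. For each class, Poisson counts were drawn from the mean profile of both libraries, with 50 genes at 50 CPM or more altered at each fold size. Only genes above a minimum level entered, and each library's total was its real total over those genes. Clustering and naming of cells were not part of this test. For true folds of 0.25, 0.5, 2 and 4, all 50 of 50 genes had the right direction in all cells and in the mesenchymal, phagocyte, vascular and lymphatic classes. The log2 ratio was within 0.25 of the truth for 50 of 50 genes at every fold in all cells and mesenchymal cells, for 48 to 50 in phagocytes and vascular cells, and for 42 to 47 in lymphatic cells. The naming rule was applied without its free RNA and sex-linked conditions, and all 24 of the 24 genes picked had a true 4-fold difference. Since noise came from counting alone and no other gene was altered by more than 2-fold, the simulation largely set this outcome. Of 40 unaltered lists per class, between 0 and 2 fell outside the central 95% of random lists. The numbers of genes that entered were 3898 for all cells, 3458 for mesenchymal cells, 3524 for phagocytes, 3636 for vascular cells and 3999 for lymphatic cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 were used.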

Results

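Single-cell RNA libraries were made from mouse soft tissue around the Achilles tendon, 1 from the injured limb 7 days after a burn with tenotomy and 1 from the contralateral uninjured limb. Both libraries were labelled burn/tenotomy, so the uninjured limb is not tissue of untreated mice. Effects of the injury beyond the injured limb may be present in both libraries. Both genotypes allow Vegfd, a growth factor for lymphatic vessels, to be overexpressed from a tetracycline-controlled transgene in the lineage of cells that express Hoxa11, a positional gene of the lower limb. The series concerns growth of lymphatic vessels and resorption of bone that forms outside the skeleton. Since both libraries carry the transgene, the comparison available here is injured against uninjured tissue of mice that carry it, and libraries of control genotype were not analysed here. The injured library held 10691 barcodes and 253050820 UMIs, with a median of 15288 UMIs per barcode. The uninjured library held 6850 barcodes and 101685524 UMIs, with a median of 11606 UMIs. After filtering, 9151 injured cells (85.6%) with a median of 17492 UMIs and 4700 uninjured cells (68.6%) with a median of 15772 UMIs remained. Mitochondrial UMIs exceeded the limit in 7.49% of injured and 26.4% of uninjured barcodes. There is 1 library per group and no replicate, so no difference was tested. Intervals are exact 95% intervals that cover counting error only.

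The first question was which cells the injured and uninjured sites held. Mononuclear phagocytes, which here are macrophages, monocytes and osteoclast-like cells, made up 30.6% of the injured library (95% interval 29.7 to 31.6, 2800 cells) and 8.87% of the uninjured library (8.08 to 9.72, 417 cells). Neutrophils, short-lived cells of acute inflammation, made up 10.9% (10.2 to 11.5, 993 cells) against 0.0851% (0.0232 to 0.218, 4 cells). Vascular endothelial cells were a smaller share of the injured library, at 12.4% (11.8 to 13.1) against 34.5% (33.1 to 35.9). Lymphatic endothelial cells, the class that carries the main VEGF-D receptor, made up 0.918% (0.733 to 1.14) of the injured and 1.79% (1.43 to 2.21) of the uninjured library, with 84 cells in each.

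Named immune cells together were 47.7% of the injured and 12.4% of the uninjured library, which lowers the share of every other class. Of the cells that were not named immune, lymphatic cells were 1.76% against 2.04%, vascular cells 23.8% against 39.3%, and mesenchymal cells 47.9% against 30.9%. Of named endothelial cells, lymphatic cells were 6.87% (5.52 to 8.43) in the injured and 4.93% (3.95 to 6.07) in the uninjured library. With each library clustered alone, this difference of 1.94 percentage points was -1.45, and the vascular difference of -22.0 points was -6.78. The lymphatic share of named endothelial cells differed by 4.99 points among cells with Xist and no Y-linked UMI and by -2.84 points among cells with a Y-linked and no Xist UMI. Among cells with Xist and no Y-linked UMI the difference in lymphatic share was 0.347 points, and among cells with a Y-linked and no Xist UMI it was -2.497 points.

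Mesenchymal cells were 25.0% of the injured (24.1 to 25.9, 2290 cells) and 27.1% of the uninjured library (25.8 to 28.4, 1272 cells). This difference of -2.04 points changed sign when the mitochondrial limit was 20%, at 0.180 points, and when list genes were left out of clustering, at 4.14 points. Different clusters held this class in the 2 libraries. The injured cells lay mainly in a fibroblast cluster (842 cells), a tenocyte-like cluster (804 cells) and a cluster of 510 cells. The marker list of chondrocytes scored highest in this last cluster, but none of its 10 top genes was a chondrocyte marker, and Acan and Sox9 were lower in it than in the tenocyte-like cluster (156.8 against 405.4 and 64.6 against 85.9 UMIs per 1000000 UMIs of the cells compared, or CPM). The uninjured cells lay mainly in 2 other fibroblast clusters (702 and 190 cells) and another tenocyte-like cluster (364 cells). The injured tenocyte-like cluster also had no tenocyte marker among its 10 top genes, which included Cthrc1, Postn and Tnc. Its best marker score was 1.21, against 5.28 in the uninjured tenocyte-like cluster, so its name rests on weaker marker levels.

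Keratinocyte-like cells, a type of skin epithelium, were 3.39% of the injured library (310 cells) and 0 of 4700 cells in the uninjured library, which allows a share of up to 0.0638%. Satellite cells or myoblasts, the precursors of muscle fibres, were 0.175% against 5.74%, and Schwann cells, the glia of nerves, 1.07% against 3.60%. Pericytes or smooth muscle cells were 4.96% against 4.66%, dendritic cells 3.43% against 2.28%, T or NK cells 2.47% against 1.00%, mast cells 0.350% against 0.128%, and myofibres 0.0328% against 0.468%. Of the pericytes or smooth muscle cells, 400 of 454 injured but 77 of 219 uninjured cells lay in 1 cluster, and 106 uninjured cells lay in another, rich in smooth muscle genes. The dendritic difference was -0.299 points among cells with Xist and no Y-linked UMI, and the mast cell difference was -0.129 points with each library clustered alone. Clusters kept unnamed, by thresholds set after the data were examined, held 4.28% of injured and 9.85% of uninjured cells.

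**Figure D1:**
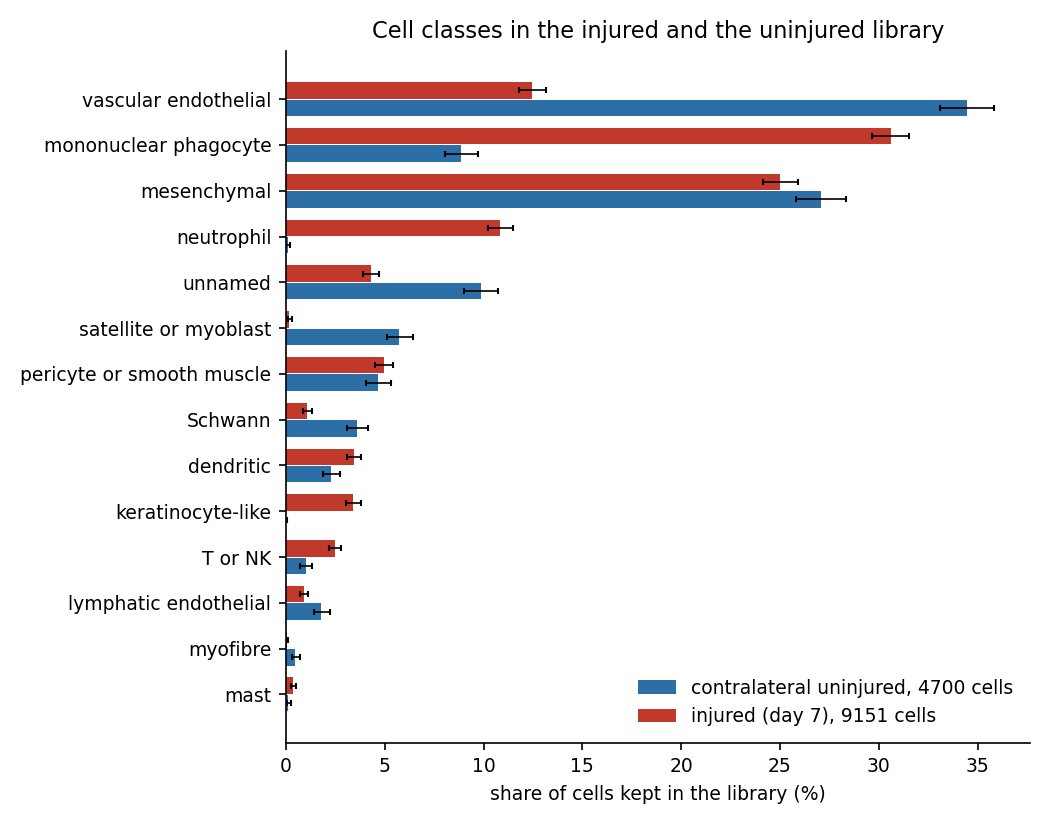
Share of each cell class among kept cells (%), as bars with exact 95% Clopper-Pearson intervals, for the injured (9151 cells) and uninjured (4700 cells) libraries. Phagocytes were 30.6% against 8.87%, and vascular endothelial cells 12.4% against 34.5%.

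Summed over all cells, the question was which genes and pathways differed between the sites. The keratin genes Krt14 and Krt16, the neutrophil genes S100a8 and S100a9 and the matrix genes Tnn and Col1a1 were higher in the injured library, and Retnla, Col22a1 and Acta1 were lower. Krt14, a basal keratinocyte keratin (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548 on mm10), was at 525.6 CPM against 0, at least 15515-fold higher. Krt16, a keratin of wounded skin, was at 186 against 0 CPM, at least 5490-fold higher. S100a8, a neutrophil alarmin (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), was 65.9-fold higher (61.5 to 70.7), at 606 against 9.20 CPM, and its partner S100a9 was at 866.5 against 14.7 CPM. Tnn, a tenascin of forming tissue, was at 148 against 0.328 CPM. Col1a1, the main fibrillar collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), was at 9299 against 4263 CPM. Retnla, a product of alternatively activated macrophages, was at 13.8 against 521 CPM. Col22a1, a collagen of tissue junctions, was at 2.38 against 134 CPM, and Acta1, the skeletal muscle actin, at 9.34 against 201 CPM.

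Among the fixed lists over all cells, the activated fibroblast list had the highest median log2 ratio, 1.51, with 8 of 12 members more than 2-fold higher. The inflammatory list followed at 1.37 (11 of 19 higher, 1 lower), then fibrillar matrix at 0.98 (8 of 17 higher), matrix proteases at 0.78 (7 of 16 higher, 2 lower), cell cycle at 0.78 (6 of 16 higher) and wound macrophage at 0.73 (6 higher, 2 lower). The tendon list had the lowest median, -1.02, with 7 of 12 members more than 2-fold lower. The resting fibroblast list was at -0.80, immediate early genes at -0.73, interferon response at -0.62, lymphatic function at -0.58 (6 of 14 lower), sprouting at -0.42 and VEGF ligands and receptors at -0.38. The osteoclast list was at 0.41 (6 of 14 higher, 2 lower), chondrogenic and osteogenic genes at 0.34 and hypoxia at 0.28. Medians for BMP and TGF-beta signalling (0.07), Hox genes (0.06), sex-linked genes (0.02), MHC class II (-0.12) and resident macrophage genes (-0.22) lay nearer to 0.

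**Figure D2:**
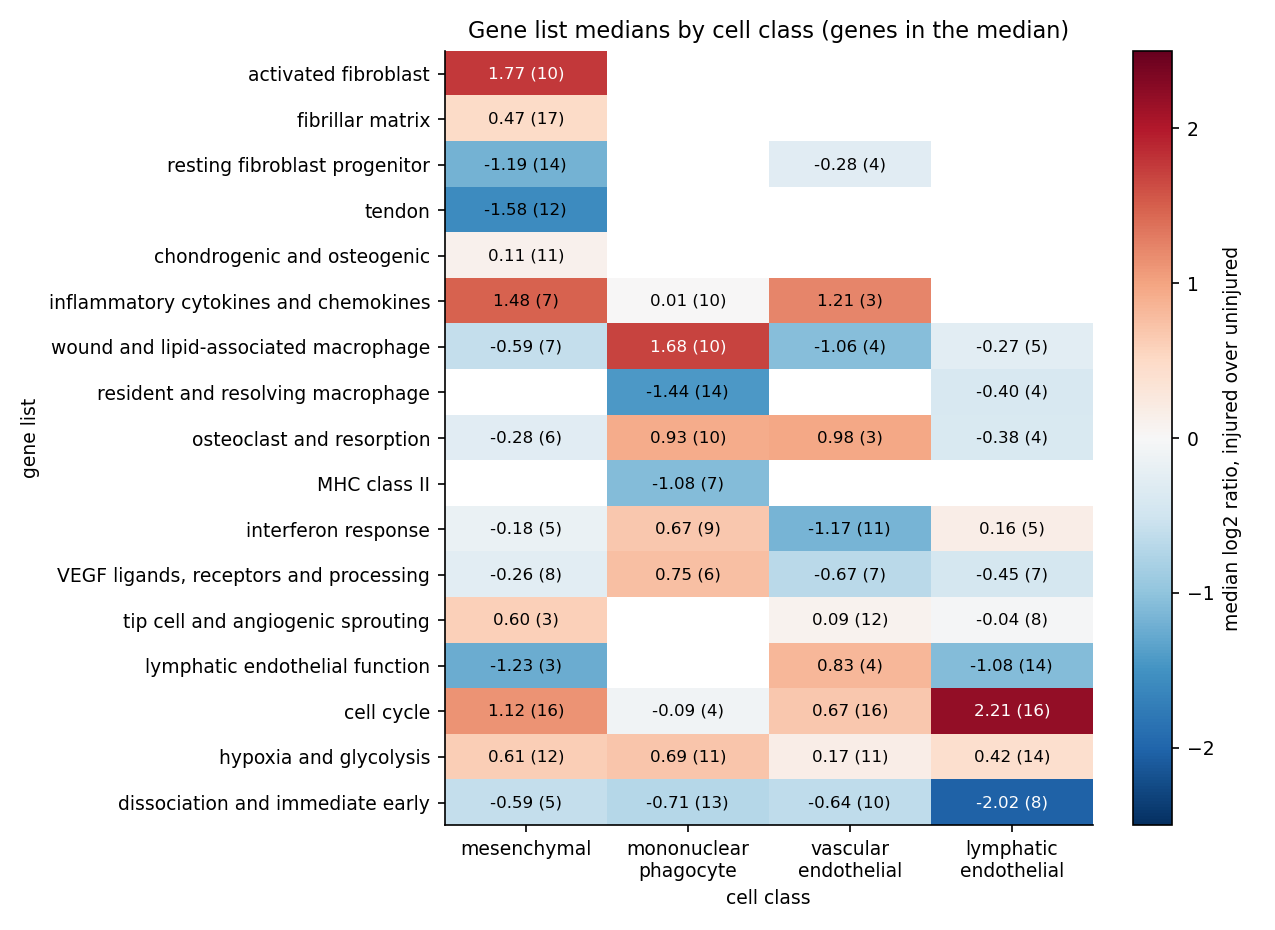
Median log2 ratio, injured over uninjured, of each fixed gene list in each main cell class, over members that the class itself expresses, with the number of genes in parentheses and blanks where fewer than 3 remained. In mesenchymal cells the activated fibroblast list was at 1.77 over 10 genes.

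In mesenchymal cells, the source of tendon and of the cartilage and bone that form after this injury, the question was which programs differed by site. Summed over the class, the injured cells had higher levels of genes of contractile, matrix-forming fibroblasts. Acta2, the smooth muscle actin of myofibroblasts, was 7.51-fold higher (1069 against 142 CPM). Cthrc1, a secreted protein of repair fibroblasts, was 6.90-fold higher (1480 against 214.5 CPM), and Tnc, a matrix protein of healing tissue, 5.43-fold higher (1303 against 240.4 CPM). Postn, which organises collagen, was at 5030 against 2499 CPM, and Lox, which cross-links it, at 856 against 286 CPM. Col1a1 differed less, at 19643 against 13111 CPM (1.498-fold). The activated fibroblast list had a median log2 ratio of 1.94 (percentile 100 among matched random lists), with 9 of 12 members more than 2-fold higher and 0 lower. In the only fibroblast cluster with over 100 cells of each library (103 injured and 702 uninjured cells), the median of this list was -0.05. There Acta2 was at 17.6 CPM (13.01 to 23.4) against 32.5 CPM (29.8 to 35.4) and Tnc at 22.4 against 105.7 CPM, while Cthrc1 was at 820.4 against 173.8 CPM.

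The chemokine genes Cxcl5, Ccl2 and Ccl7 were also higher in injured mesenchymal cells. Cxcl5, a neutrophil attractant, was at 442.6 CPM (438.7 to 446.6) against 0.255 CPM. It was the first of the top genes of the injured cluster of 510 cells, so its level was not even over the class. Ccl2, a monocyte attractant, was 9.78-fold higher (148 against 15.1 CPM), and the related Ccl7 was at 168 against 24.3 CPM. Saa3, an acute phase protein, was at 102.8 against 0 CPM, at least 941-fold higher. Of inflammatory list members that the class itself expresses, the median was 1.48 over 7 genes. In the shared fibroblast cluster the inflammatory median was 1.15 over 17 genes, without that limit to expressed members. There Ccl2 was at 202.5 against 14.5 CPM. Lists of other cell types were also higher there, with MHC class II at 2.20, wound macrophage at 0.71 and resident macrophage at 0.75. Over the class MHC class II and wound macrophage were at 1.10 and -0.15. Over members that the class itself expresses, the wound median was -0.59, and 0 MHC class II genes remained. The class MHC class II median was -0.074 with doublets kept and -0.105 among cells with Xist and no Y-linked UMI. Tnn was at 317 against 0.728 CPM, Chl1, an adhesion molecule, at 202 against 4.15 CPM, and Lrrc15, a marker of activated fibroblasts, at 179 against 12.1 CPM. The Wnt modulators Sfrp1 and Sfrp2 were at 736 against 44.7 CPM and 743 against 45.5 CPM.

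Summed over the class, genes of resting fibroblasts and mature tendon were lower. Gsn, an actin-severing protein abundant in resting fibroblasts, was at 658 against 9017 CPM, and Clec3b, a progenitor marker, at 249 against 929 CPM. The tendon regulators Scx and Mkx were at 118 against 268 CPM and 12.8 against 96.1 CPM, and the tendon matrix genes Tnmd, Fmod and Chad at 244 against 727, 219 against 939.5 and 3.62 against 277.5 CPM. The resting fibroblast list had a median of -1.19 (percentile 0), with 8 of 14 members more than 2-fold lower and 1, Sfrp2, higher. The tendon list had a median of -1.58 (percentile 0), with 8 of 12 lower and 0 higher. Without the tenocyte-like cluster held mostly by the uninjured library, the tendon median was 1.22. In the shared fibroblast cluster the resting fibroblast median was 0.14 and the tendon median -0.56.

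Of the chondrogenic and osteogenic list, 2 of 12 members were more than 2-fold higher, 1 was lower and 9 were within 2-fold. Acan, the main cartilage proteoglycan, was 25.2-fold higher (22.1 to 29.0), at 200.1 CPM (197.5 to 202.8) against 7.93 CPM (6.92 to 9.06). Sox9, the regulator of cartilage fate, was 2.46-fold higher (64.8 against 26.4 CPM), and Runx2, an early bone regulator, was at 108.5 against 54.5 CPM. Later bone genes were near the limit of detection, with 4 against 0 UMIs of Sp7, 9 against 1 of Ibsp and 25 against 9 of Bglap. The median of the list was 0.07 (percentile 66.6). In the shared fibroblast cluster Sox9 was lower, at 16.2 CPM (11.8 to 21.7) against 27.9 CPM (25.4 to 30.5). BMP and TGF-beta genes had a median of -0.17 with 5 of 17 members lower, among them the ligands Bmp2 (1.73 against 24.6 CPM) and Bmp4 (3.84 against 45.9 CPM) and their target Id1 (11.8 against 39.7 CPM). Fibrillar matrix was at 0.47 (percentile 98.0), cell cycle at 1.12, hypoxia at 0.52, proteases at 0.24, immediate early genes at -0.56, VEGF genes at -0.20 and Hox genes at -0.16. In the shared cluster fibrillar matrix was at -0.11, hypoxia at -0.10 and cell cycle at 0.10.

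Genes that set osteoclast formation were compared because the series concerns bone resorption. Tnfsf11, which encodes the osteoclast-inducing ligand RANKL (ENSMUSG00000022015, chromosome 14, 78277445 to 78308043), was at 24.0 CPM (23.1 to 24.9) in injured mesenchymal cells and 0.0728 CPM (0.00882 to 0.263) in uninjured ones, from 2620 against 2 UMIs, a ratio of 329.9 (91.2 to 2726). Tnfrsf11b, which encodes its decoy receptor osteoprotegerin (ENSMUSG00000063727, chromosome 15, 54250619 to 54278484), was lower, at 7.58 CPM (7.07 to 8.12) against 62.7 CPM (59.8 to 65.7). Csf1, a growth factor for the macrophage lineage (ENSMUSG00000014599, chromosome 3, 107741048 to 107760469), was at 48.3 against 104.6 CPM. In the shared fibroblast cluster Tnfrsf11b had the other direction, at 21.3 CPM (16.2 to 27.6) in injured and 5.99 CPM (4.86 to 7.30) in uninjured cells, Csf1 was at 135.3 against 135.5 CPM, and Tnfsf11 had 0 against 1 UMI.

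**Figure D3:**
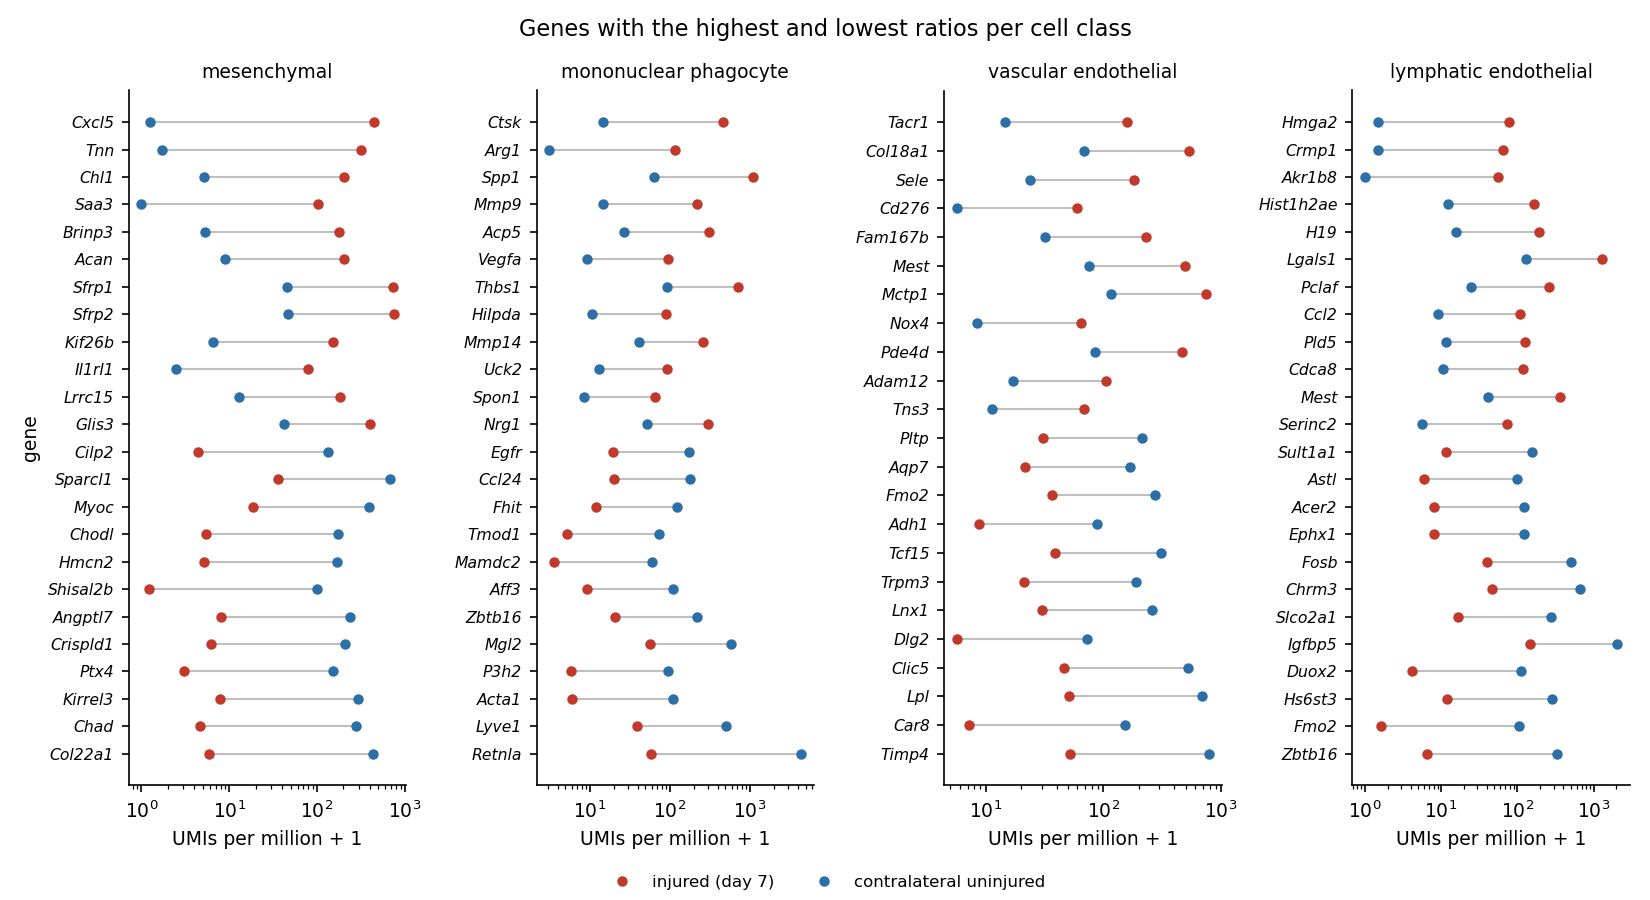
Levels of the 12 genes with the highest and the 12 with the lowest ratio in each main class, as CPM plus 1 on a log axis, with 1 dot per library and 1 vascular gene not shown. In mesenchymal cells Cxcl5 was at 442.6 against 0.255 CPM, and in phagocytes Ctsk was at 461.6 against 13.5 CPM.

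In mononuclear phagocytes, the question was how these cells differed by site and whether osteoclast genes were present. The class lay in different clusters in the 2 libraries. A macrophage cluster rich in resident genes held 19.4% of injured and 46.3% of uninjured phagocytes (544 and 193 cells), a monocyte cluster held 23.0% and 4.32%, and another macrophage cluster held 44.8% and 47.5% (1254 and 198 cells). Ctsk, the collagen-degrading protease of osteoclasts (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362), was 34.1-fold higher (27.7 to 42.5), at 461.6 CPM (455.1 to 468.1) against 13.5 CPM (10.9 to 16.7). Acp5, the tartrate-resistant phosphatase of osteoclasts (ENSMUSG00000001348, chromosome 9, 22126727 to 22135711), was 12.0-fold higher (312.7 against 26.2 CPM), and the protease Mmp9 16.0-fold higher (218.6 against 13.7 CPM). The osteoclast list had a median of 0.77, with 5 of 12 members more than 2-fold higher and 0 lower, and with a pseudocount of 1 CPM the median was 1.64. A cluster of 299 injured cells with a median of 1521 UMIs held 72.4% of the injured phagocytes' Ctsk UMIs in its 75 cells with 5000 or more UMIs. Its other 224 cells, with a median of 1180 UMIs, held 0.347% of the injured phagocytes' Acp5, Ctsk and Mmp9 UMIs. Per UMI, these 3 genes together were at 440.5 CPM (371.9 to 518) in the 224 cells, from 146 UMIs. In the 75 deeper cells they were at 13301 CPM. The 10 top genes of this cluster included the macrophage genes C1qa and C1qb as well as Acp5 and Ctsk. In the phagocytes outside that cluster (2501 and 415 cells), Ctsk was at 133 against 13.5 CPM and Acp5, Ctsk and Mmp9 together at 366.8 CPM (360.9 to 372.8) against 53.4 CPM (48.0 to 59.3). In the resident-rich macrophage cluster Ctsk was at 23.8 CPM (20.8 to 27.2) against 17.3 CPM (12.98 to 22.5) and the osteoclast median was 0.04. In the other macrophage cluster Ctsk was at 84.3 against 11.6 CPM and the median was 0.50.

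Wound macrophage genes were higher in the injured phagocytes. Arg1, an arginine-degrading enzyme, was 54.8-fold higher (116.7 against 2.13 CPM), Spp1, the secreted protein osteopontin, 17.9-fold higher (1115 against 62.2 CPM), and Fabp5, a lipid carrier, 14.9-fold higher (1686 against 113 CPM). Vegfa, the main angiogenic ligand, was at 95.7 against 8.36 CPM, Thbs1, a matrix regulator of TGF-beta, at 715 against 92.7 CPM, and Nrg1, a ligand for glia and muscle, at 303 against 51.4 CPM. The wound list had a median of 1.61, with 9 of 14 members higher and 1, Cd36, lower, and it was 0.90 in the resident-rich and 1.73 in the other macrophage cluster. Retnla was at 56.9 against 4445 CPM. The tissue-resident markers Lyve1, Cd163, Folr2 and Timd4 were at 38.1 against 503, 160 against 676, 172.5 against 461 and 1.58 against 43.6 CPM. The resident list had a median of -1.44 with 10 of 14 lower in the class, and of -0.73 and -0.51 in the resident-rich and the other macrophage cluster, with 4 members lower in each. The antigen presentation genes Cd74 (3856 against 9458 CPM) and H2-Aa (2388 against 4909 CPM) were lower, and the MHC class II list was at -1.08 with 5 of 7 lower, and at -1.74 and -1.75 within the macrophage clusters. Interferon response was at 0.67, hypoxia at 0.63, inflammatory genes at 0.11 and immediate early genes at -0.71. Mesenchymal lists were higher in the same cells, with fibrillar matrix at 0.92 (7 of 17 higher), 1.29 in the resident-rich and 0.56 in the other macrophage cluster, and activated fibroblast at 0.58. Cell cycle was at 0.28, and at -0.0264 with a mitochondrial limit of 5%.

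In vascular endothelial cells, the question was whether blood vessels of the injured site differed in angiogenic genes. Plvap, a component of fenestrated and sprouting vessels, was 3.64-fold higher (1482 against 407 CPM), Aplnr, a receptor of sprouting vessels, 2.58-fold higher (424.5 against 165 CPM), and Angpt2, a destabiliser of vessels, was at 57.2 against 25.6 CPM. The sprouting list was at -0.03 over the class, and at 0.58 (percentile 99.98) and 0.20 (percentile 91.8) within the 2 clusters that held over 100 cells of each library. Col18a1, a vessel basement membrane collagen, was at 536 against 67.1 CPM, Sele, an adhesion molecule for leukocytes, at 180 against 22.7 CPM, and Nox4, an oxidase, at 63.6 against 7.47 CPM. Genes with the lowest ratios included Lpl, a lipase of the capillary wall (49.8 against 696 CPM), Timp4, a protease inhibitor (50.7 against 796 CPM), Car8 (6.28 against 152 CPM) and Tcf15, a capillary regulator (37.6 against 309 CPM). The VEGF receptor genes Flt1 (916 against 2086 CPM) and Nrp1 (301 against 798 CPM) were lower too. The interferon list had a median of -1.17 (percentile 0) with 6 of 11 members lower, including Isg15 (92.1 against 218 CPM) and Ifit1 (25.4 against 92.9 CPM). Within the 2 shared clusters it was at -0.21 and -0.01. Cell cycle was at 0.67, with Birc5 at 62.5 against 23.6 CPM, VEGF genes at -0.33 and immediate early genes at -0.63. Lists of other cell types were higher in the same cells, with fibrillar matrix at 1.20 (11 of 17 higher), 0.74 and 0.94 in the shared clusters, activated fibroblast at 1.05 and MHC class II at 0.71. This MHC class II median was -0.20 with doublets kept and -0.21 among cells with Xist and no Y-linked UMI. The injured cells lay mainly in 2 clusters (507 and 323 cells) and the uninjured cells in another (1098 cells, with 99 injured).

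In lymphatic endothelial cells, the question was how the vessels that VEGF-D acts on differed by site, with 84 cells per library. Genes of dividing cells were higher in the injured cells. Birc5, a mitotic regulator, was 9.21-fold higher (206 against 22.4 CPM), Top2a, a replication topoisomerase, was at 275 against 52.4 CPM, and Mki67, a marker of dividing cells, at 167 against 33.6 CPM. The cell cycle list had a median of 2.21, with 14 of 16 members higher and 0 lower. Among cells with Xist and no Y-linked UMI the median was 1.26, and such cells were 64.6% of injured and 29.4% of uninjured lymphatic cells assigned a sex. Hmga2, a chromatin protein of fetal and growing tissue, was at 77.5 against 0.509 CPM, from 250 against 1 UMI, a ratio of 152 (27.1 to 6043). Lgals1, a galectin, was at 1274 against 129.7 CPM, and the fetal growth genes H19 and Mest at 191 against 14.8 and 366 against 40.7 CPM.

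Several genes of lymphatic function were lower. Ccl21a, which guides dendritic cells into lymphatic vessels and has close paralogs, was at 2069 against 8443 CPM. Mmrn1 and Reln, secreted proteins of lymphatic endothelium, were at 683 against 2261 CPM and 522 against 1273 CPM. Foxc2, a regulator of lymphatic valves, was at 19.8 against 101 CPM, and Ackr4, a chemokine scavenger, at 0 against 40.7 CPM, at least 43.8-fold lower. The identity regulator Prox1 was at 515 against 959 CPM and Lyve1 at 1213 against 951 CPM. The lymphatic function list had a median of -1.08 (percentile 0.04), with 7 of 14 members lower and 1, Angpt2, higher, and as a mean over cells the median was -0.65. Immediate early genes, which also respond to dissociation, were at -2.08 with 12 of 13 lower, including Fosb (39.1 against 499 CPM) and Egr1 (78.1 against 547 CPM). Sprouting was at 0.17 and VEGF genes at -0.33. Lists of other cell types were higher in the same cells, with fibrillar matrix at 1.59 (13 of 17 higher) and MHC class II at 1.66 (4 of 7 higher). The MHC class II median was -0.48 among cells with a Y-linked and no Xist UMI.

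The levels of Vegfd and of VEGF receptor genes were compared because Vegfd is the gene of the transgene. A 3' tag may miss a transgene with another 3' end, so these values do not measure the transgene alone. Vegfd (ENSMUSG00000031380, chromosome X, 164373378 to 164402650) was at 196.3 CPM (193.6 to 198.9) in injured and 66.8 CPM (63.8 to 70.0) in uninjured mesenchymal cells, 2.94-fold higher (2.80 to 3.08). These cells held 94.2% and 88.1% of each library's Vegfd UMIs. A Vegfd UMI was found in 64.9% of injured (median 45469 UMIs) and 24.4% of uninjured mesenchymal cells (median 19818 UMIs), against 1.82% and 1.92% of phagocytes (median 13796 and 14938 UMIs), which should lack the gene. After thinning to 2000 UMIs the mesenchymal shares were 16.9% and 5.34%. Pericytes or smooth muscle cells had 42.5 against 10.2 CPM, and their shared cluster (400 and 77 cells) 45.9 CPM (41.7 to 50.5) against 16.5 CPM (9.62 to 26.4). Among mesenchymal cells with Xist and no Y-linked UMI the ratio was 4.53 (285.5 against 63.1 CPM). Among those with a Y-linked and no Xist UMI it was 2.73 (2.47 to 3.01), at 122.5 against 44.95 CPM. Vegfd thus also differed within the injured library between these 2 sets of cells, which come from different mice. In the shared fibroblast cluster Vegfd was at 157.0 against 96.6 CPM, a ratio of 1.62 (1.46 to 1.81). Hoxa11, the gene whose locus drives the recombinase (ENSMUSG00000038210, chromosome 6, 52242106 to 52245810), was at 14.6 CPM (13.9 to 15.3) in injured and 15.1 CPM (13.7 to 16.6) in uninjured mesenchymal cells, a difference within counting error. Ccbe1, which aids processing of lymphatic growth factors (ENSMUSG00000046318, chromosome 18, 66045302 to 66302741), was at 85.9 against 61.6 CPM.

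The VEGF receptor genes Flt4 and Kdr were lower in the injured endothelial cells. Flt4, which encodes VEGFR-3 (ENSMUSG00000020357, chromosome 11, 49609263 to 49652739), was at 441.1 CPM (418.5 to 464.7) in injured and 603.2 CPM (569.3 to 638.5) in uninjured lymphatic cells. Kdr, which encodes VEGFR-2 (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458), was at 323.7 CPM (304.3 to 343.9) against 610.3 CPM (576.3 to 645.8) in lymphatic cells and at 426.2 CPM (419.9 to 432.6) against 682.9 CPM (673.7 to 692.2) in vascular cells. The co-receptor Nrp2 (ENSMUSG00000025969, chromosome 1, 62703285 to 62818695) was at 731 against 554 CPM in lymphatic cells, a log2 ratio of 0.40 that was -0.50 among cells with a Y-linked and no Xist UMI.

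**Figure D4:**
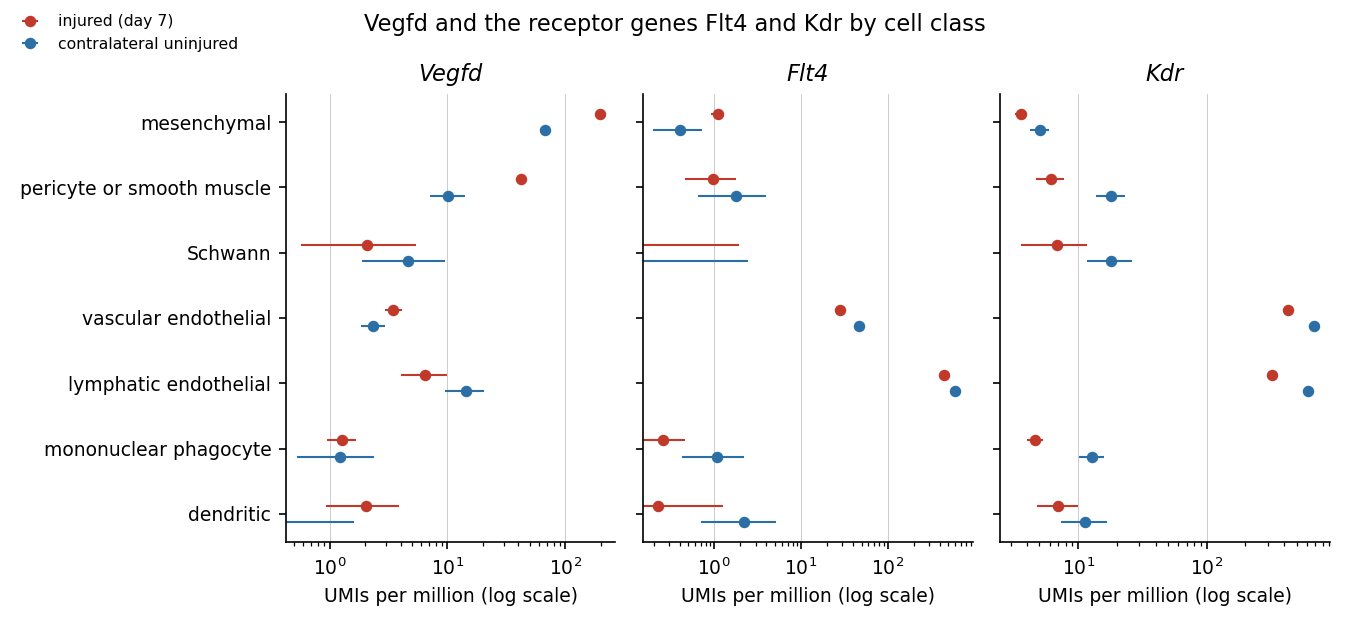
Vegfd, Flt4 and Kdr (CPM, log axes) by cell class, with a dot per library and exact 95% Poisson intervals; a line with no dot is a count of 0. Vegfd in mesenchymal cells was at 196.3 CPM in the injured and 66.8 CPM in the uninjured library.

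Transcripts of dividing cells were compared at equal depth, as the share of cells with an Mki67 or Top2a UMI after thinning to 2000 UMIs. Cells with fewer UMIs were left out, 460 injured and 185 uninjured ones, among them 213 of 2800 injured and 8 of 417 uninjured phagocytes. The share was 8.12% (7.56 to 8.72) of 8691 injured and 2.99% (2.51 to 3.53) of 4515 uninjured cells. Of lymphatic endothelial cells it was 33.3% (23.2 to 44.7, 27 of 81) against 2.5% (0.304 to 8.74, 2 of 80). Mesenchymal cells had 8.71% (7.58 to 9.95) against 1.86% (1.18 to 2.78), vascular endothelial cells 10.2% (8.45 to 12.1) against 3.61% (2.75 to 4.65), and pericytes or smooth muscle cells 10.96% against 0.463%. Neutrophils, which do not divide, had 2.59% (1.68 to 3.80, 25 of 965) in the injured library, and the 4 uninjured ones were too few for such a background. In phagocytes the shares were 5.91% and 4.64% (2.82 to 7.16), a difference within counting error. The overall difference of 5.13 points was 17.8 points without thinning and 2.98 points when thinned to 1000 UMIs, and the lymphatic difference of 30.8 points was 55.9 points without thinning.

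**Figure D5:**
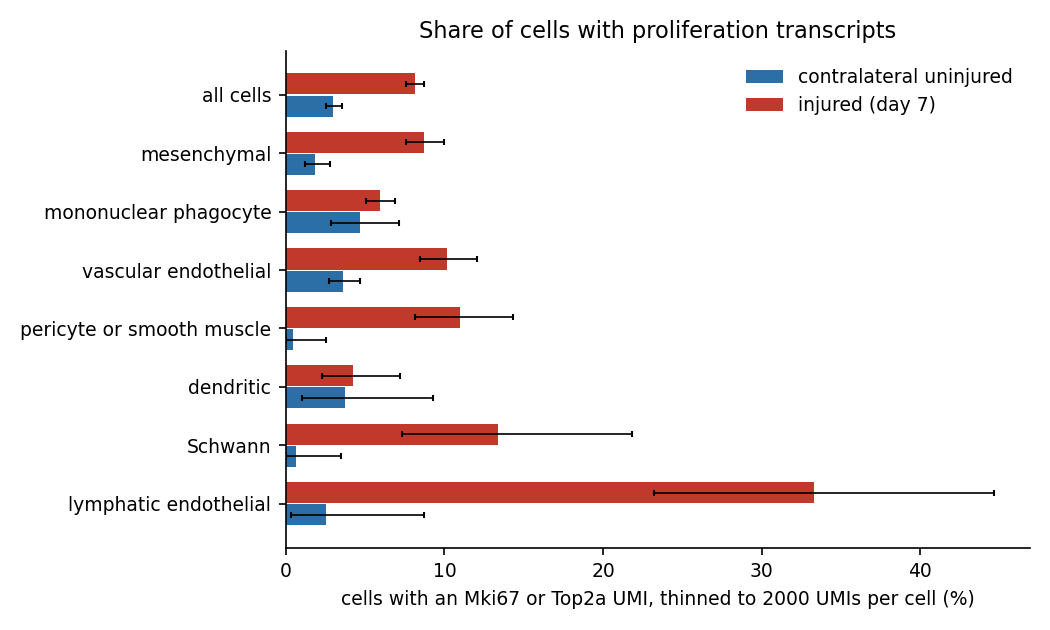
Share of cells (%) with an Mki67 or Top2a UMI after thinning to 2000 UMIs per cell, over cells with at least that many, as bars per class and library with exact 95% Clopper-Pearson intervals. Lymphatic endothelial cells were at 33.3% in the injured and 2.5% in the uninjured library.

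The design names male and female mice, so the sexes of the cells were compared. Xist, expressed from the inactive X chromosome, was found without Y-linked genes in 38.9% of injured and 51.2% of uninjured cells, and Y-linked genes without Xist in 38.0% and 32.3%. Both were found in 10.3% and 3.60% of cells, and in 2.74% and 0.617% with a minimum of 2 UMIs for each. Each library thus held cells of both sexes. Of cells assigned a sex, Xist-only cells were 50.6% (49.4 to 51.8) in the injured and 61.3% (59.7 to 62.8) in the uninjured library. Among phagocytes they were 51.6% against 78.3%, among lymphatic endothelial cells 64.6% (51.8 to 76.1) against 29.4% (19.0 to 41.7), and among injured neutrophils 17.1% (14.1 to 20.5).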

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

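Of the tests reported here, those of free keratin RNA, of free mesenchymal RNA, of Vegfd by sex of the cells and of osteoclast genes in single macrophage clusters were chosen only after the result was seen. Barcodes removed by the filters entered no comparison, and in the injured library they held more UMIs of some genes per UMI than the removed barcodes of the uninjured library did. In barcodes under 500 genes, S100a8 and S100a9 together were at 1081 CPM against 5.57 CPM, Lyz2 at 1333 against 66.8 CPM, Col1a1 at 1513 against 354 CPM, and Krt14 and Krt5 together at 179.1 against 0 CPM. In barcodes over 10% mitochondrial UMIs, S100a8 and S100a9 were at 1843 against 71.5 CPM, Lyz2 at 1073 against 398 CPM, Col1a1 at 2369 against 1705 CPM, and Krt14 and Krt5 at 642.5 against 0 CPM. The kept cells had the same directions, such as 1473 against 23.9 CPM for S100a8 and S100a9, so these differences are not particular to removed barcodes. Other genes were lower in the removed barcodes of the injured library, with Acta1 and Ckm together at 162 against 273 CPM under 500 genes and at 10.6 against 142 CPM over 10% mitochondrial UMIs, and Pecam1 at 69.3 against 86.8 CPM and 176 against 252 CPM.

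Some differences between the libraries had opposite signs in cells with Xist only and cells with Y-linked genes only, though for each of them except Nrp2 one of the pair lay within its counting error. The values that follow are the difference among Xist-only cells minus that among Y-only cells, and none of these differences of differences was tested. It was 2.84 percentage points for the share of lymphatic endothelial cells (0.347 ± 0.535 and -2.497 ± 0.957), 2.88 points for pericytes or smooth muscle cells (1.93 ± 1.13 and -0.951 ± 1.43) and -2.83 points for dendritic cells (-0.299 ± 0.914 and 2.53 ± 0.946). For the lymphatic share of named endothelial cells it was 7.83 points (4.99 ± 2.54 and -2.84 ± 3.01), and for Nrp2 in lymphatic endothelial cells it was 466.1 CPM (294 ± 97.9 and -172 ± 64.3). The ± values are half-widths of 95% counting intervals.

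Keratinocyte-like cells were found in the injured library alone. Free keratin RNA is argued against as the whole cause, since 72.9% of these cells (67.6 to 77.8, 226 of 310) held more Krt14 and Krt5 UMIs than free RNA at the level of the removed injured barcodes, 642.5 CPM, would give by counting error in any injured cell. The cells were named by their keratins, which this limit over all injured cells allows for, and for the cells below it free RNA was not excluded. Skin taken with the injured tissue is a candidate explanation, since genes of melanocytes, another skin cell type, were 6.50-fold higher (5.66 to 7.49) in the other injured cells than in the uninjured ones. The single genes differed widely, at 144.3-fold for Dct, 8.64-fold for Tyrp1, 2.68-fold for Pmel and 1.81-fold for Mlana, and Schwann lineage cells can also express some of them. An injured skin edge that grew into the wound, a biological explanation, was not tested.

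Osteoclast genes were higher in injured phagocytes. Free RNA of mesenchymal cells is argued against for Ctsk by the ratio of Ctsk to Col1a1 UMIs. This ratio was 110.2 times as high (108.3 to 112.0) in injured phagocytes as in injured mesenchymal cells. Acp5 and Mmp9 were not tested this way, and neither was free RNA of other classes, such as the 993 injured neutrophils. Shallow barcodes are argued against by phagocytes of 5000 UMIs or more, in which Acp5, Ctsk and Mmp9 together were 18.7-fold higher (16.8 to 20.8) in the injured library (1006 against 53.9 CPM). Within macrophage clusters shared by both libraries the median of the osteoclast list was 0.04 and 0.50, against 0.77 in the class, though clustering on expression itself sets cells rich in osteoclast genes apart. In the latter cluster Ctsk was at 84.3 against 11.6 CPM, Acp5 at 135.6 against 43.4 CPM and Mmp9 at 68.0 against 0 CPM. Other osteoclast markers were mixed in phagocytes outside the shallow osteoclast-like cluster. There Dcstamp was at 5.498 CPM (4.796 to 6.275) against 7.455 CPM (5.515 to 9.856), and Calcr had 2 against 4 UMIs. Ocstamp was at 4.62 against 0.761 CPM, Atp6v0d2 at 33.9 against 16.1 CPM, and Oscar had 14 against 1 UMI. More frequent osteoclast-like cells and higher expression within macrophages may both contribute, and these hypotheses were found and examined on the same pair of libraries. Whether the Vegfd transgene contributes was not tested, since libraries of control genotype were not analysed here.

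Vegfd was higher in injured mesenchymal cells. A different mix of male and female cells is argued against as the whole cause, since the smaller of the ratios in the 2 sets of cells was 2.73 (2.47 to 3.01). A different mix of mesenchymal clusters cannot be told apart from a difference within cells, since the ratio in the fibroblast cluster shared by both libraries was 1.62 (1.46 to 1.81), between 1 and the ratio of the whole class. A link to the driver gene also stays open, since after thinning the share of injured cells with a Vegfd UMI in those with Hoxa11 over those without was 0.945, with shares of 38.1% (32.4 to 44.1) and 40.4% (38.1 to 42.6), and Hoxa11 is read after the recombination it may have driven. Injury itself, which the design names, stays a hypothesis.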

How the results depend on the processing

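The alternatives with cells of 1 sex only, doublets removed by rank, members at free RNA level left out, and single clusters left out or taken alone were chosen after seeing the data. Over 250 results and 2005 values under alternatives, 1014 stayed within counting error, 969 moved by more and 22 reversed. For shares, a sign change counted as reversed only where the main difference lay beyond counting error. For lists, it did so only where the main median was extreme among random lists. Other sign changes counted as stayed or moved, so 22 understates them. In shared clusters, vascular sprouting went from -0.03 to 0.58 and 0.20, and mesenchymal chondrogenic and osteogenic genes from 0.07 to -0.28. By kind, 120 of 167 values of shares stayed, 40 moved and 7 reversed; for lists these were 559, 471 and 14 of 1044, for named genes 289, 431 and 0 of 720, for Vegfd and receptors 16, 15 and 1 of 32, for cycling 29, 11 and 0 of 40, and for sexes 1, 1 and 0 of 2. For the values that follow the cause was not tested, except where an alternative removes the cells or genes it names.

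Shares are differences in percentage points. The mesenchymal difference of -2.04 was -6.22 with a mitochondrial limit of 5%, and it reversed to 0.180 with a limit of 20% and to 4.14 with list genes left out of clustering. The vascular difference of -22.0 was -24.3 with 200 or more genes, -24.9 with 5% mitochondrial, -27.5 at resolution 0.4, -15.4 at resolution 1.5, -23.6 with list genes left out, -6.78 with each library clustered alone and -24.0 with doublets removed by rank. With each library clustered alone, the phagocyte difference of 21.7 was 24.1, the mast cell difference reversed from 0.222 to -0.129, and the lymphatic share of endothelial cells reversed from 1.94 to -1.45.

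Among Xist-only cells, the differences were 19.9 for phagocytes, -18.1 for vascular cells, 4.99 for lymphatic cells of endothelial, and reversed to 0.347 for lymphatic and -0.299 for dendritic cells. Among Y-only cells they were -4.13 for mesenchymal cells, 25.6 for phagocytes, -24.8 for vascular cells, -2.497 for lymphatic cells, and reversed to -2.84 for lymphatic cells of endothelial.

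Lists are median log2 ratios. With a median-of-ratios scale, activated fibroblast genes in mesenchymal cells went from 1.94 to 2.07, tendon from -1.58 to -1.45, resident macrophage genes from -1.44 to -1.38 and lymphatic function from -1.08 to -0.99. As a mean over cells the medians were 2.10 (activated fibroblast), -1.47 (tendon), -1.01 against -1.17 (vascular interferon) and -0.65 (lymphatic function), and Vegfd in mesenchymal cells gave 1.63 against 1.49. With 5% mitochondrial, activated fibroblast was 1.99, tendon -1.06, vascular interferon -1.27, lymphatic cell cycle 1.64 against 2.21, and phagocyte cell cycle reversed from 0.28 to -0.0264. With a pseudocount of 1, the phagocyte osteoclast list was 1.64 against 0.77 and lymphatic cell cycle 2.38. With doublets kept, activated fibroblast was 1.90, tendon -1.60, and MHC class II reversed from 1.10 to -0.074 in mesenchymal and from 0.71 to -0.20 in vascular cells. At resolution 0.4 vascular interferon was -1.05.

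With members at free RNA level left out, activated fibroblast was 1.77, phagocyte osteoclast 0.93, and the mesenchymal osteoclast list reversed from 0.30 to -0.28 and phagocyte cell cycle to -0.09024. Without the tenocyte-like cluster, activated fibroblast was 2.76 and tendon reversed to 1.22. Without the shallow cluster, resident macrophage was -1.38. In the fibroblast cluster shared by both libraries, taken alone, tendon was -0.56, and the list medians reversed for activated fibroblast (-0.05109), fibrillar matrix (from 0.47 to -0.11), resting fibroblast (from -1.19 to 0.14) and hypoxia (from 0.52 to -0.10). In the shared macrophage clusters, osteoclast was 0.04271 and 0.50 and resident macrophage -0.73 and -0.51. In the shared vascular clusters, interferon was -0.21 and -0.01101, and BMP and TGF-beta genes reversed from -0.29 to 0.0225 in 1 of them. The size or direction of these class values depends on which clusters each library holds. In Xist-only cells, activated fibroblast was 2.04, tendon -1.54, Vegfd 2.09, resident macrophage -1.18, vascular interferon -0.87, lymphatic function -0.81, lymphatic cell cycle 1.26, and MHC class II reversed to -0.11 in mesenchymal and -0.21 in vascular cells. In Y-only cells these were 1.57, -1.84, 1.35, -1.79, -1.28, -1.18 and 2.04, the phagocyte osteoclast list was 1.07, and in lymphatic cells MHC class II reversed from 1.66 to -0.48 and Nrp2 from 0.40 to -0.50.

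The cycling difference over all cells of 5.13 points was 2.98 when thinned to 1000 UMIs and 17.8 without thinning, and in lymphatic cells 30.8 was 55.9 without thinning. Depth limits small classes, such as the lymphatic class (84 cells, 3225694 and 1966258 UMIs) and the Schwann class (98 and 169 cells, 1909083 and 1508131 UMIs), and genes with few UMIs such as Sp7. Xist-only and Y-only cells come from different mice, so the alternatives by sex mix sex with mouse, and none addresses variation between mice of the same sex.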

Other observations

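Other classes with 50 or more cells in both libraries were compared by the same lists. In pericytes or smooth muscle cells, the cell cycle list had a median log2 ratio of 2.80, with 14 of 16 members more than 2-fold higher in the injured library. Mki67 was 32.0-fold higher (86.4 against 2.70 CPM). The class lay in different clusters in the 2 libraries, and in the cluster with 400 injured and 77 uninjured cells Mki67 was at 96.6 CPM (90.4 to 103.2) against 4.86 CPM (1.58 to 11.3). Lists of other cell types were higher in the class too, with MHC class II at 2.13 (6 of 6 higher) and fibrillar matrix at 1.51 (15 of 17 higher), and fibrillar matrix was at 1.20 in Schwann and 0.49 in dendritic cells. In Schwann cells, cell cycle was at 3.47 with 15 of 16 higher, and Top2a was at 251 against 0.663 CPM, from 1 UMI in the uninjured library, a ratio of 378 (67.6 to 14977). Immediate early genes were at -1.70 with 12 of 13 lower. This class too lay in different clusters, with 69 injured and 49 uninjured cells in 1 cluster. Another cluster, rich in myelin genes, held 29 injured and 120 uninjured cells. Tnc was 40.1-fold higher, while the myelin gene Mbp (1005 against 6091 CPM) was lower and the lineage regulator Sox10 was at 228 against 214 CPM. The dendritic class was 1 cluster, and none of its 10 top genes was a dendritic marker. They included Cd74, H2-Aa and Retnla, and 5 of 13 resident macrophage genes were more than 2-fold lower in the injured cells, with 0 higher. Whether both libraries hold the same cells under this name was not tested. In dendritic cells, the interferon list was at 1.09 with 6 of 11 higher, including Irf7 (52.1 against 9.17 CPM). Ccr7 and Fscn1, members of the fixed dendritic marker list chosen here after their values were seen, were at 224.5 against 3.93 CPM (57.1-fold, 29.96 to 125) and 147 against 2.62 CPM.

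The mesenchymal clusters differed in the genes that set osteoclast formation. Tnfrsf11b was at 188.4 CPM (179.3 to 197.8) in the uninjured tenocyte-like cluster and, in the fibroblast cluster shared by both libraries, 21.3 CPM in injured and 5.99 CPM in uninjured cells. Tnfsf11 was at 48.3 CPM in the injured cluster of 510 cells without a chondrocyte marker among its top genes. In the injured library it was at 14.9 CPM in the tenocyte-like cluster, which had no tenocyte marker among its top genes. In the fibroblast cluster of the injured library it was at 12.7 CPM. Injured T or NK cells had Tnfsf11 at 55.1 CPM, and injured neutrophils had Csf1 at 206 CPM. Removed barcodes under 500 genes were rich in haemoglobin, at 405822 CPM in the injured and 509907 CPM in the uninjured library.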
